A study of Homo sapiens with 6 samples.

How the data were processed

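Single-cell RNA sequencing libraries were made from cultured primary human astrocytes, glial cells grown from tissue and not an established cell line. Per the labels, 6 libraries were prepared with a droplet 3' kit (10x Genomics), 1 for each condition, so each group holds 1 library. The conditions were no treatment, a mixture of 5 cytokines for 24 h or 48 h, ponesimod for 48 h, and the cytokine mixture together with ponesimod for 24 h or 48 h. Each cytokine was used at 25 ng/mL and ponesimod at 1 µM, per the labels. The labels give no time for the untreated library, and say nothing of separate cultures or donors.

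The reads were processed with Cell Ranger 4.0.0 and Seurat 3.1 against GRCh38, per the submitters' processing notes. The single table used here holds 1 line per cell. It carries 48851 cells, with no values per gene, so no gene could be tested or named. Counts of unique molecular identifiers (UMIs) per cell were deposited by the authors as unnormalised totals over all genes, beside the number of genes with a UMI. The mitochondrial percent is the share of a cell's UMIs from mitochondrial genes, as deposited: times the UMIs it gave a whole number (within 1e-06) in 100% of cells. The SCT total per cell is a score here: per the file headers it is the sum of counts corrected by Seurat's SCTransform, a depth normalisation whose settings are not given in the sources used here. Its library medians lay near the libraries' median UMIs. The deposited cluster numbers run from 1 to 17 and no cell carries number 13, so 16 clusters were analysed. How the clusters were made, and what type of cell each holds, are not given in the sources used here.

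Cells had been filtered before deposit. No cell had fewer than 501 UMIs or 311 genes or more than 7.5% mitochondrial UMIs, and the highest UMI total was between 2.32 and 2.70 times the median in each library. The filter's limits and the treatment of doublets are not given in the sources used here, and a doublet caller could not be run without gene values. Cells were assigned to libraries by the library name in the table, which matches the bracketed part of 1 sample title each. The table's own treatment column gave the same condition for all cells.

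For each library the number of cells, the median and quartiles of UMIs, genes and mitochondrial percent, and the share of cells in each cluster were computed with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. Figures were drawn with matplotlib 3.10.9. Each share has an exact Clopper-Pearson 95% interval. These intervals cover counting error only and not the variation between cultures. A share of 0 is given with the limit that 3 cells of the library's total would make. For 7 pairs of libraries, the distance in cluster composition is the sum of the absolute differences in share divided by 2, from 0% for identical to 100% for wholly separate mixes. Beside it stand the mean and the upper limit of the central 95% of 10000 pairs of libraries drawn at random from the pooled mix. With 1 library per group and cells not being replicates, no p-value between conditions was computed.

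The distance was tested on simulated data: for 2 simulated libraries of 8495 cells with 10% of cells moved between clusters it gave 11.5%, and with no difference 1.25%, beside a chance value of 2.06%. The distance is never below 0, so counting noise raises it. Depth was simulated apart, with 2 clusters whose membership depended on a cell's UMIs alone. The distance of 11.4% made so fell to 0.199% after weighting over UMI bins, an outcome this setting made likely. That simulation does not cover clusters that keep their place relative to their library's median UMIs, where weighting can itself create a distance.

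The clusters named were fixed by rule before the data were examined: those whose share differed by 5 percentage points or more in any of the 7 pairs, and the largest cluster of each library. This gave clusters 1, 2, 3, 4, 5, 6, 8, 10 and 11. Clusters 7, 9, 12, 14, 15 and 16 are mentioned after their values were seen. Gene lists had been fixed too and could not be used. The other settings, chosen before the data were examined, were leaving out the 1% of cells with the highest UMIs per library, requiring 1000 genes and at most 10% mitochondrial UMIs (the second part removed no cell), keeping cells within a common range of 11423 to 20330 UMIs (2709 to 4663 cells per library), weighting the libraries to 1 distribution over 10 bins of UMIs, taking means, and leaving out clusters whose median UMIs were under 4948 (clusters 14 and 15). Another clustering, and shares by cell cycle phase, had been intended and were not run, since the table has 1 clustering and no phase. A limit of 1.5 times the library's median UMIs, and a denominator of cytokine-associated clusters, were added after seeing the data. The cytokine-associated clusters (3, 8, 11 and 16) held under 0.5% of cells in both libraries without cytokines, over 0.5% in at least 1 library, and in every library with cytokines at least 0.1 points more than without treatment. Cells could not be thinned to 1 depth because gene values are not used here.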

Results

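Gene expression was profiled in single primary human astrocytes to ask whether ponesimod alters their response to inflammatory cytokines. Ponesimod is a modulator of a sphingosine 1-phosphate receptor used in multiple sclerosis. The cytokine mixture held tumour necrosis factor α, interferon-γ and the interleukins 1β, 6 and 17. The values available per cell were the UMI total, the number of genes detected, the mitochondrial percent and the authors' cluster number. Clusters are therefore described by number, without a cell type or marker gene. Where a treatment changes the genes that define a cluster, a cell can move between clusters without any gain or loss of cells, so shares describe where cells were placed.

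The 6 libraries, 1 per condition, held 8495 untreated cells, 6673 cells after 24 h and 7310 after 48 h of cytokines, 9678 cells after 48 h of ponesimod, and 9607 cells after 24 h and 7088 after 48 h of cytokines with ponesimod. The target was 10000 cells per library, per the labels. Total UMIs were 129148276 in the untreated library, 141744773 after 24 h and 146684559 after 48 h of cytokines, 122479757 with ponesimod alone, and 135152900 and 131791892 after 24 h and 48 h of cytokines with ponesimod. Because each condition has 1 library, no difference between conditions could be tested against replicates, and the intervals cover counting error only.

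Cytokine exposure was compared with no treatment to describe the astrocyte response. The mix of clusters differed widely. Cluster 1 was the largest cluster of the untreated library, at 38.8% of cells (exact 95% interval 37.8 to 39.8), and held 18.5% (17.6 to 19.5) after 24 h and 17.1% (16.3 to 18) after 48 h of cytokines. Cluster 3 held 0.141% of untreated cells (12 of 8495, interval 0.0730 to 0.247), against 18.2% (17.3 to 19.2) at 24 h and 15.1% (14.3 to 15.9) at 48 h. Cluster 8 held 3 untreated cells, 0.0353% of that library (0.00728 to 0.103), against 6.25% (5.68 to 6.86) and 14.0% (13.2 to 14.8). Cluster 11 held 2 untreated cells, 0.0235% (0.00285 to 0.0850), against 3.82% (3.37 to 4.31) and 6.96% (6.39 to 7.57).

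Cluster 10 was present without cytokines at 1.00% (0.80 to 1.24), and held 6.46% (5.88 to 7.08) at 24 h and 7.28% (6.69 to 7.90) at 48 h. The small cluster 16 held 0 of 8495 untreated cells, where 3 cells would make 0.0353% and the exact interval reached 0.0434%. It held 0.644% (0.467 to 0.867) and 0.848% (0.651 to 1.09) of cytokine-treated cells. Clusters 4 and 6 were smaller with cytokines. Cluster 4 held 13.5% of untreated cells, 7.07% at 24 h and 5.29% at 48 h, and cluster 6 held 8.65%, 3.13% and 4.57%. Cluster 2 held 10.8% of untreated cells, 16.03% at 24 h and 12.2% at 48 h. Weighting over UMI bins took the cluster 2 difference from 5.26 to 9.85 points at 24 h and from 1.40 to 4.15 at 48 h, and the cluster 4 difference at 24 h from -6.42 to -10.7. Cluster 5 held 10.2%, 11.3% and 6.22%, and its difference from no treatment at 48 h was -3.96 points over all cells and -5.30 within a common range of UMIs.

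Over all cells, 4 of the 16 clusters were larger and 3 smaller by at least 5 points after 24 h of cytokines, and 4 were larger and 2 smaller after 48 h. The distance in composition from the untreated library was 40.6% at 24 h and 44.4% at 48 h, where chance draws gave means of 2.12% and 2.13%. Both distances rest on the same untreated library, for which the labels give no time.

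**Figure D1:**
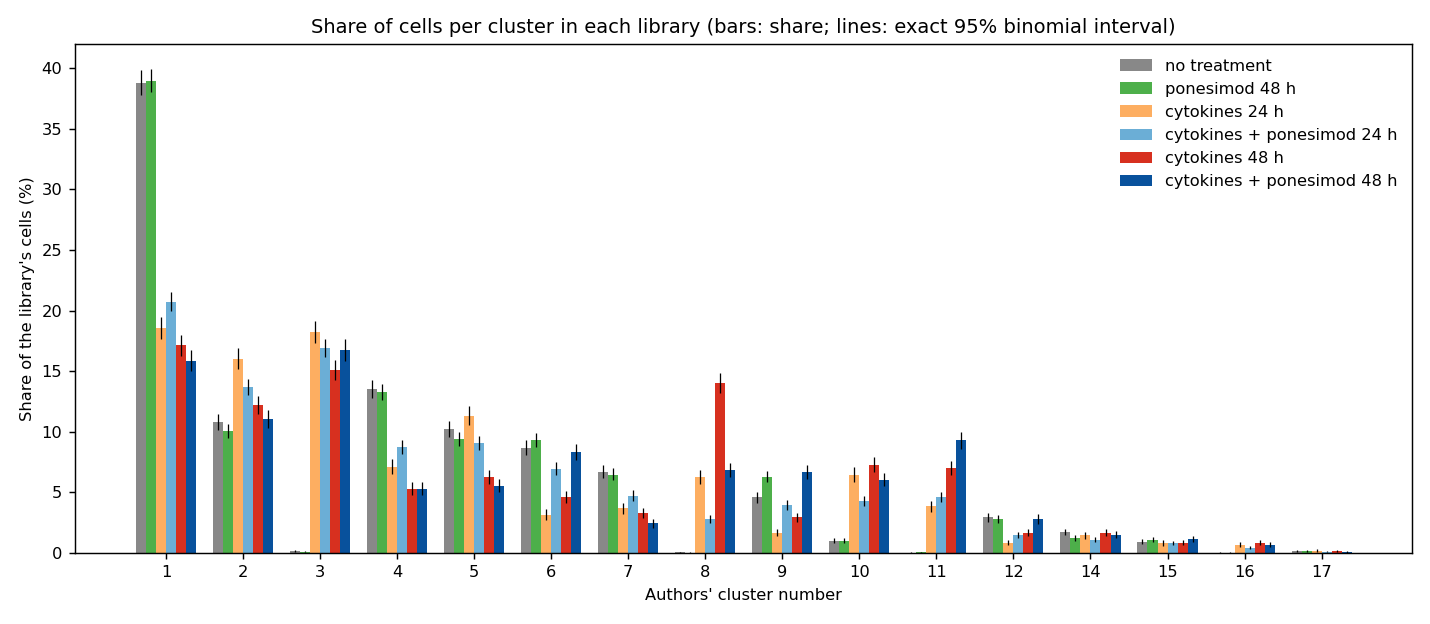
Share of each library's cells (%, vertical axis) in each of the authors' clusters (horizontal axis), with exact 95% binomial intervals as lines and 1 bar per library. Clusters 3, 8, 11 and 16 are almost empty in both libraries without cytokines, and cluster 8 is larger with cytokines alone (14.0% at 48 h) than with ponesimod added (6.83%).

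Ponesimod alone for 48 h was compared with no treatment, to describe resting astrocytes with and without it. The labels give no time for the untreated library, so a difference in time cannot be told apart from treatment. The mix of clusters was close to that of the untreated library. Cluster 1 held 38.99% of cells (38.01 to 39.97) against 38.8%, cluster 4 held 13.3% against 13.5%, and cluster 6 held 9.31% against 8.65%. Cluster 3 held 0.0723% (7 of 9678, 0.0291 to 0.149) and cluster 8 held 0.0103% (1 cell, 0.000262 to 0.0576). Cluster 16 held 0 of 9678 cells, where 3 cells would make 0.0310% and the exact interval reached 0.0381%. Over all cells no cluster differed by 5 points, and the widest gap was in cluster 9, with 6.28% (5.81 to 6.78) against 4.57% (4.13 to 5.03). Among cells within a common range of UMIs the gap in cluster 9 changed direction, to -0.78 points, and clusters 1 and 4 differed by -7.11 and 6.76 points. The distance in composition was 2.71%, where chance draws gave a mean of 1.64% and an upper limit of 2.54% for the central 95% of draws. It was 10.9% within the common range of UMIs, which spans a higher part of the ponesimod library than of the untreated one.

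Ponesimod in the presence of cytokines was compared with cytokines alone at the matching time, the comparison that bears most directly on the study's question. Cluster 8 was smaller with ponesimod at both times. At 24 h it held 2.75% (2.43 to 3.09) with ponesimod and 6.25% without, a ratio of 0.44. At 48 h it held 6.83% (6.25 to 7.44) with ponesimod and 14.0% without, a ratio of 0.49. Weighted over UMI bins the differences of -3.50 and -7.17 points became -2.29 and -5.28. Cluster 10 was also smaller, at 4.25% (3.85 to 4.67) against 6.46% at 24 h and 6.04% (5.49 to 6.62) against 7.28% at 48 h, and its 24 h difference of -2.21 points became -3.40 after weighting and -4.85 within the common range.

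The small cluster 16 held 0.396% (0.280 to 0.543) against 0.644% at 24 h and 0.649% (0.476 to 0.865) against 0.848% at 48 h, with intervals that overlap at both times. Clusters 3 and 11 did not follow cluster 8. Cluster 11 held 4.59% (4.18 to 5.03) with ponesimod against 3.82% at 24 h, and 9.27% (8.60 to 9.97) against 6.96% at 48 h. Its 24 h difference went from 0.77 to 1.69 points with weighting. Cluster 3 held 16.9% (16.1 to 17.6) against 18.2% at 24 h, and 16.7% (15.9 to 17.6) against 15.1% at 48 h; the 24 h difference of -1.35 points became 2.19 after weighting over UMI bins and 3.90 within the common range. Clusters 3, 8, 11 and 16 together held 24.6% (23.7 to 25.5) of cells with ponesimod and 28.9% (27.9 to 30.0) without at 24 h, and 33.5% (32.4 to 34.6) and 36.9% (35.8 to 38) at 48 h. Within these 4 clusters, the part held by cluster 8 was 11.2% (9.93 to 12.5) with ponesimod and 21.6% (19.8 to 23.5) without at 24 h, and 20.4% (18.8 to 22.1) and 37.9% (36.1 to 39.8) at 48 h.

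Cluster 6, one of those smaller with cytokines, was larger when ponesimod was added. It held 6.93% (6.43 to 7.46) against 3.13% (2.73 to 3.58) at 24 h, and 8.30% (7.66 to 8.96) against 4.57% (4.10 to 5.07) at 48 h. Cluster 9 held 3.91% (3.53 to 4.32) against 1.65% (1.36 to 1.98) at 24 h, and 6.63% (6.06 to 7.24) against 2.91% (2.54 to 3.33) at 48 h. Within a common range of UMIs the cluster 9 difference went from 2.27 to -0.34 points at 24 h and from 3.72 to 2.24 at 48 h. Cluster 12 held 1.46% against 0.839% at 24 h and 2.78% against 1.64% at 48 h, differences of 0.62 and 1.14 points that were 1.91 and 2.01 within the common range.

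Cluster 1 held 20.7% (19.9 to 21.5) with ponesimod against 18.5% at 24 h, and 15.8% (14.99 to 16.7) against 17.1% at 48 h; the 24 h difference was -2.34 points within the common range. Cluster 4 held 8.70% against 7.07% at 24 h, and 5.29% in both libraries at 48 h. Cluster 2 held 13.7% against 16.03% and 11.1% against 12.2%, and cluster 5 held 9.07% against 11.3% and 5.54% against 6.22%. Weighting over UMI bins raised the 24 h difference in cluster 4 from 1.63 to 6.03 points and took that in cluster 2 from -2.37 to -8.08 points. Within the common range they were 8.58 and -9.07 points. At 48 h the cluster 2 difference of -1.11 points became -2.74 after weighting and -2.89 within the common range.

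Over all cells no cluster differed by 5 points at 24 h between the libraries with and without ponesimod, and cluster 8 did at 48 h. Clusters 2 and 4 passed 5 points at 24 h in both settings that match absolute UMIs. Cluster 6 did so at 48 h within the common range, at 6.27 points. The distance in composition was 12.3% at 24 h and 12.8% at 48 h, where chance draws gave means of 2.12% and 2.31%. It was 19.6% at 24 h after weighting over UMI bins, and 24.2% within the common range. The library with ponesimod at 24 h had a median of 13204 UMIs per cell and that without had 19896. Matching absolute UMIs therefore counts a higher part of the library with ponesimod than of that without. Cluster 4 stood at 1.40 and 1.43 times its library's median with and without ponesimod, and cluster 2 at 0.81 and 0.82. Unequal depth alone can thus widen the gaps in these clusters, so the wider gaps are not read as effects of ponesimod.

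**Figure D2:**
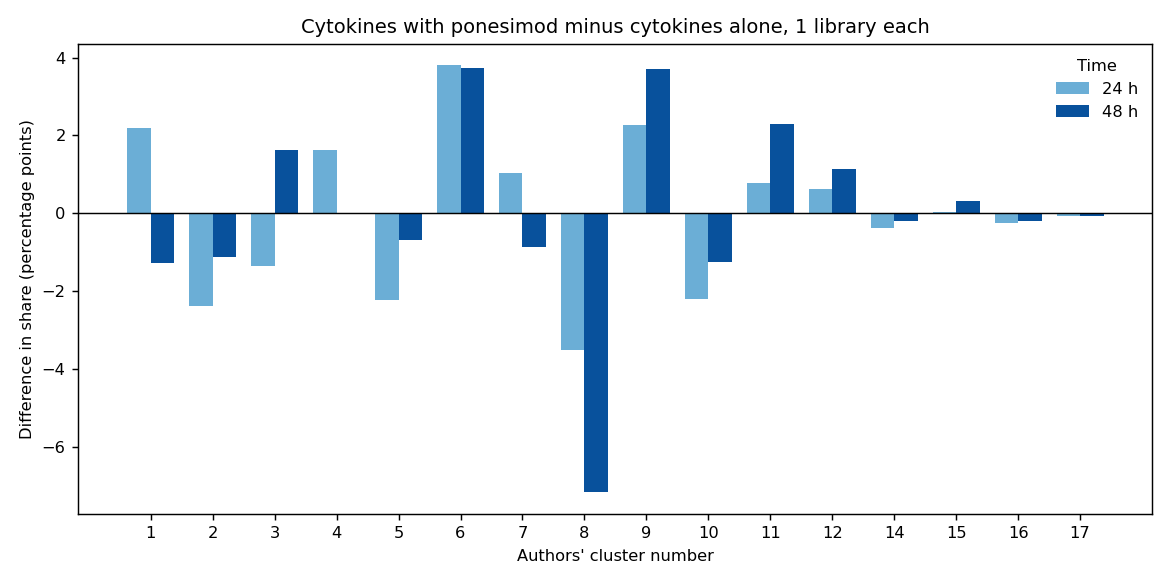
Difference in share (percentage points, vertical axis) between cytokines with ponesimod and cytokines alone, for each of the authors' clusters (horizontal axis) at 24 h and 48 h, with 1 library on each side of every difference. Cluster 8 has the lowest bars, -3.50 points at 24 h and -7.17 at 48 h, and cluster 6 has bars of 3.80 and 3.73 points.

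Duration of cytokine exposure was compared at 48 h against 24 h. Cluster 8 was larger at 48 h both without ponesimod, at 14.0% against 6.25% (ratio 2.24), and with it, at 6.83% against 2.75% (ratio 2.48). Cluster 11 was larger as well, at 6.96% against 3.82% without and 9.27% against 4.59% with ponesimod. Cluster 5 was smaller, at 6.22% against 11.3% and 5.54% against 9.07%. With ponesimod the largest difference was in cluster 1, at -4.89 points over all cells and -2.61 within the common range of UMIs. Without ponesimod the cluster 1 difference was -1.42 points over all cells. The distance in composition between the times was 15.7% without ponesimod and 16.9% with it, where chance draws gave means of 2.29% and 2.13%. Within the common range of UMIs these distances were 18.8% and 26.9%. With ponesimod, cluster 3 then differed between the times by -7.51 points, against -0.15 over all cells, cluster 4 by -7.25 against -3.41, and cluster 6 by 5.63 against 1.36.

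UMIs and genes per cell differed between the libraries. The median number of UMIs per cell was 14037 without treatment (quartiles over cells 10318 and 19194), 19896 after 24 h and 18514 after 48 h of cytokines, 11798 with ponesimod, and 13204 and 16835 after 24 h and 48 h of cytokines with ponesimod. Relative to the untreated library the medians were 1.42 and 1.32 times as high with cytokines alone and 0.84 times with ponesimod. With ponesimod added to cytokines they were 0.66 times those with cytokines alone at 24 h and 0.91 times at 48 h. The median of genes detected was 3542 without treatment, 3898 and 3813 with cytokines, 3165 with ponesimod, and 3174 and 3608 with cytokines and ponesimod.

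The number of genes followed the number of UMIs. Within the common range of UMIs the medians were 3673 without treatment, 3518 and 3524 with cytokines, 3541 with ponesimod, and 3369 and 3474 with both. Cytokines alone thus gave 1.10 and 1.08 times as many genes as no treatment over all cells, and 0.96 times at both times within the common range. The corrected totals had library medians of 14076 without treatment, 19940 and 18534 with cytokines, 11819 with ponesimod, and 13214 and 16854 with both, in the order of the UMI medians. Each lay near its library's own UMI median, so the corrected totals are not read apart from depth.

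The mitochondrial percent of UMIs had a median of 5.79% (quartiles 5.10 and 6.46) in the untreated library and 5.79% (5.14 and 6.43) with ponesimod alone. It was 5.32% (4.70 and 5.98) after 24 h and 5.03% (4.39 and 5.73) after 48 h of cytokines. With ponesimod added it was 4.59% (4.06 and 5.15) at 24 h, a difference of -0.73 points from cytokines alone, and 5.68% (5.04 and 6.31) at 48 h, a difference of 0.66 points. No cell in any library exceeded 7.5%, so values above that are not represented.

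**Figure D3:**
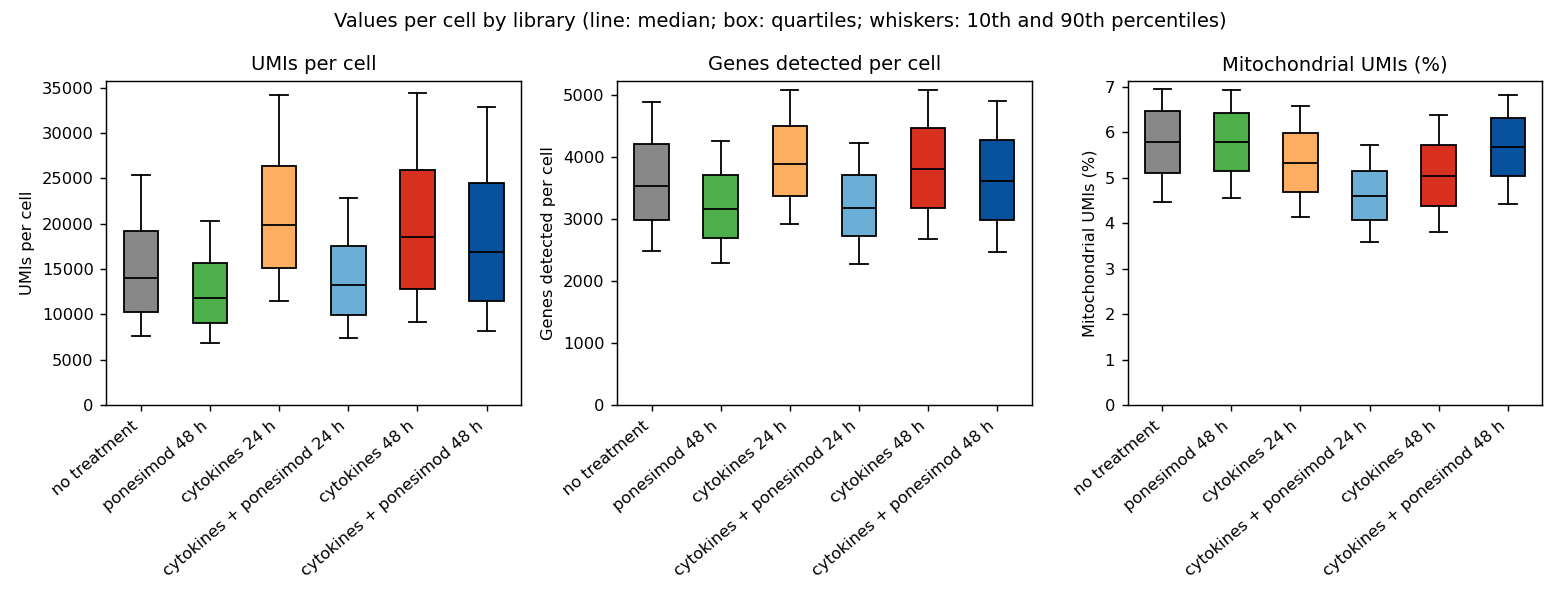
UMIs per cell, genes detected per cell and mitochondrial UMIs (%) in each of the 6 libraries, with the median as a line, quartiles as the box and the 10th and 90th percentiles as whiskers. Median UMIs per cell run from 11798 with ponesimod alone to 19896 after 24 h of cytokines, and the mitochondrial median is lowest, at 4.59%, after 24 h of cytokines with ponesimod.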

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

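The weighting to 1 mix of clusters, the counts by cluster and the relation of UMIs to cells were chosen after the values had been seen, and so was the reading of the weighting over UMI bins, a setting fixed beforehand, as a test of the mitochondrial shift. With 1 library per condition, the differences between effects were not tested. Each was singled out because its direction was opposite in the 2 settings compared.

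The mitochondrial percent moved in opposite directions with ponesimod at the 2 times. Against cytokines alone it was -0.73 points at 24 h and 0.66 points at 48 h, which sets the effects 1.38 points apart. The same 4 libraries read over time gave -0.29 points from 24 h to 48 h without ponesimod and 1.10 points with it. This is the same contrast rearranged, so the 1.38 points between them add no evidence. The mix of clusters is argued against as the cause of the opposite directions, since weighted to 1 mix the differences were -0.72 and 0.67 points. The mitochondrial percent was lower in 14 of 15 clusters at 24 h and higher in 14 of 15 at 48 h. Cluster 15, a low-UMI cluster, was the exception at both times. Weighted to 1 distribution of UMIs the differences were -0.81 and 0.62 points, which argues against a dependence on a cell's own UMI total. This weighting compares different parts of libraries of unequal depth, so it cannot decide on an effect tied to a whole library's depth. A shift that runs through nearly all clusters may come from handling of whole cultures or libraries, or from ponesimod acting differently at the 2 times, and the single libraries leave both open.

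UMIs and genes per cell also moved in opposite directions over time. Median UMIs changed by -1383 from 24 h to 48 h with cytokines alone and by 3631 with ponesimod added, 5014 apart. Median genes changed by -85.5 and 434, 520 apart, over all cells. With UMIs taken into account the opposite directions of genes were not seen: the ratios of 48 h to 24 h were 1.00185 without and 1.03 with ponesimod within the common range of UMIs, and 1.02 and 1.01 weighted over UMI bins. A candidate explanation is that a similar number of UMIs was shared out among different numbers of cells. Across the 6 libraries the slope of log mean UMIs per cell on log cells was -1.27, where equal totals would give -1, so totals were somewhat lower in libraries with more cells. Totals varied by 6.50% (CV) against 20.5% for the means. Pearson's r between cells and mean UMIs was -0.97 (exact permutation p = 0.00833, 6 libraries), Spearman's rho was -0.94 (exact permutation p = 0.0167), and r was -0.94 over 4 libraries without the 2 libraries farthest from the median cell number, both of them at its upper end. This was 1 relation, so no adjustment applies, and UMIs per cell contain the cell number by construction. RNA content that differs between conditions stays open, since 3 of the 4 libraries with cytokines also held the fewest cells.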

How the results depend on the processing

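Of 590 values recomputed under an alternative, 438 stayed within counting error, 140 moved, and 12 that had differed beyond counting error changed direction. The 140 include 12 cell counts, which a filter lowers by definition. They also include the share differences taken within the cytokine-associated clusters, which have another denominator. For these values, having moved is not a result of a comparison with counting error. Among 543 ratios and differences, 31 changed direction in all, since 19 whose first value was within counting error did so too. The 7 pairs are, in order, cytokines at 24 h and at 48 h and ponesimod against no treatment (A, B, C), ponesimod added to cytokines at 24 h and 48 h (D, E), and 48 h against 24 h without and with ponesimod (F, G). Ratios of median genes per cell changed direction within the common range of UMIs for A (0.958), B (0.959) and F (1.00185), and moved to 0.964 for C, 0.958 for D, 0.986 for E and 1.03 for G. Weighted over UMI bins they changed direction for A (0.921), B (0.939), D (1.00326) and F (1.02), and moved to 0.944 for C, 0.994 for E and 1.01 for G. Genes per cell rise with UMIs per cell, so these ratios are limited by depth.

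The UMI ratio of G was 1.32 from means. The mitochondrial difference became -0.41 (A), -0.66 (B), -0.83 (D), 0.56 (E) and 1.15 (G) within the common range, -0.70 (B), -0.81 (D) and 1.17 (G) when weighted, and -0.40 (A), -0.68 (B), 0.56 (E, 0.557) and 0.98 (G) from means. Corrected totals differed by 4823 (A), 3460 (B), -1935 (C), -5609 (D) and 2748 (G) within the common range, and by 4777, 3411, -1994, -5517 and 2636 when weighted. Since each corrected median lay near its library's own UMI median, these differences restate unequal depth and are not a separate result.

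Distances in composition were 46.3 (A), 46.1 (B), 10.9 (C), 24.2 (D), 14.6 (E), 18.8 (F) and 26.9% (G) within the common range, and 43.8 (A), 4.57 (C), 19.6 (D) and 19.4% (G) when weighted. A fixed range of UMIs takes a different part of each library by construction. The cluster 8 difference with ponesimod kept its direction throughout: -2.29 points at 24 h and -5.28 at 48 h when weighted, -5.75 at 48 h within the range, and, added after seeing the data, -10.4 and -17.5 points of the cytokine-associated clusters. Within the range, 5 share differences beyond counting error changed direction: -2.34 points for cluster 1 (D), 1.19 for cluster 2 (G), 1.52 for cluster 4 (F), and -0.78 (C) and -0.34 (D) for cluster 9. Others that changed direction from within counting error include cluster 3 (D, 3.90 within the range and 2.19 weighted), clusters 1 and 4 (C, -7.11 and 6.76 within the range) and cluster 1 (F, 0.77 weighted). Of 422 share differences, 16 crossed 5 points, among them cluster 2 (D, -9.07 and -8.08), cluster 4 (D, 8.58 and 6.03) and cluster 6 (E, 6.27 within the range). Clusters 1, 2 and 9 lay below their library's median UMIs and cluster 4 above it in every library. Settings that match absolute UMIs between libraries of unequal depth can therefore change their shares by themselves. How much of the changes comes from this was not tested.

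Without the 1% of cells with the highest UMIs the libraries held 8410 (untreated), 6606 and 7236 (cytokines), 9581 (ponesimod), 9510 and 7017 (both) cells; with at least 1000 genes, 8361, 6622, 7232, 9518, 9469 and 6952. Another clustering and shares by cell cycle phase were not run, since the table holds neither. No paired test was run, because each condition has 1 library and no label pairs cultures. Matched by time, the difference with ponesimod had the same direction at 24 h and 48 h in 12 of 16 clusters. Random signs would give 8, though shares within a library are not independent. The 12 include cluster 15, with a difference of 0.03 points at 24 h, and cluster 16, whose intervals overlapped at both times. Some of the directions counted thus lie within counting error.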

Other observations

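The limit on UMIs and the denominator of cytokine-associated clusters were added after the data had been seen, and the tests of that denominator and of the distance to the untreated library were chosen after their results had been seen. Comparing clusters within a library avoids differences in depth between libraries. Clusters 4, 7 and 12 had more UMIs per cell than their library's median in all 6 libraries, by 1.36 to 1.55 times for cluster 4, 1.17 to 1.32 times for cluster 7 and 1.05 to 1.36 times for cluster 12. Clusters 1, 2, 9, 10, 14 and 15 were below it in all 6, cluster 9 at 0.60 to 0.85 times. With cytokines, some clusters lay farther from the library median at 48 h than at 24 h and others nearer. Cluster 3 stood at 1.11 times the library median at 24 h and 1.28 at 48 h without ponesimod, and at 1.05 and 1.38 with it. Cluster 8 stood at 1.04 and 1.25 without and at 1.02 and 1.34 with ponesimod, and cluster 5 at 0.98 and 1.21 and at 1.09 and 1.37. Cluster 9 went the other way, from 0.80 to 0.60 and from 0.72 to 0.61, and cluster 1 from 0.92 to 0.78 and from 0.95 to 0.81. Cluster 12 came nearer the median, from 1.22 to 1.05 without and from 1.27 to 1.07 with ponesimod. Clusters 4 and 7 came nearer without ponesimod, from 1.43 to 1.36 and from 1.24 to 1.22, and moved away with it, from 1.40 to 1.55 and from 1.17 to 1.31.

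Clusters 14 and 15 had medians of 2299 and 2262 UMIs per cell, against 14844 over all cells. They held between 1.06% and 1.70% (cluster 14) and between 0.779% and 1.10% (cluster 15) of each library. In cluster 15 the median mitochondrial percent was 0.37% after 48 h of cytokines with ponesimod (78 cells) and 2.60% to 3.61% in the other libraries.

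The 2 libraries without cytokines held 28 cells in clusters 3, 8 and 11. The barcode of 1 of these (3.57%, exact interval 0.0904 to 18.3) was also listed in a library with cytokines, against 158 of all 18173 cells of those 2 libraries (0.869%, 0.740 to 1.02).

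The lower share of cluster 8 with ponesimod was weighed against technical explanations. If unequal UMIs per cell had made it because placement follows absolute UMIs, weighting over UMI bins should have brought the ratio of shares near 1. The ratio stayed at 0.56 at 24 h and 0.53 at 48 h. Weighting cannot decide on unequal depth as such, since it can shift clusters that keep their place relative to the library's median. Cluster 8 stood at 1.04 times that median without and 1.02 times with ponesimod at 24 h. Unequal depth between the libraries therefore stays open. If the upper limit on UMIs had removed cluster 8 cells, the ratio should have risen among cells with at most 1.5 times their library's median. The ratio was 0.41 and 0.46. At 48 h cluster 8 stood at 1.34 times the library's median with ponesimod and 1.25 times without. The added limit can then remove more of cluster 8 with ponesimod and lower the 48 h ratio by itself. A weaker placement of cells in all cytokine-associated clusters is argued against by the ratio within those clusters, 0.52 and 0.54. Variation between cultures stays open, since it was not replicated, and so does an effect of ponesimod on the genes that define the cluster, which may move cells to neighbouring clusters without any loss.

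A hypothesis is that ponesimod moves the mix of cytokine-treated cells toward that of untreated cells. The distance to the untreated library was 30.5% with and 40.6% without ponesimod at 24 h, a difference of -10.04 points, and 40.9% and 44.4% at 48 h, a difference of -3.53 points. Weighted over UMI bins the differences were -14.3 points at 24 h and -1.80 at 48 h. In 2000 random reshufflings of cells between the libraries with and without ponesimod, the central 95% of unweighted differences ran from -1.60 to 1.47 points at 24 h and from -1.63 to 1.53 at 48 h. The weighted ones ran from -1.62 to 1.48 and from -1.65 to 1.63, so all 4 values lay outside, the weighted 48 h value by the least. That value fell short of 3.13%, the upper limit of the central 95% of chance distances between 2 libraries. This bound was chosen after the results had been seen, and is made for 1 distance and not for a difference of 2 distances. By cluster, the difference with ponesimod had the direction of the untreated share in 14 of 16 at 24 h and 8 of 16 at 48 h. This count includes clusters that went past the untreated share. At 48 h cluster 9 held 6.63% with and 2.91% without ponesimod, against 4.57% untreated. For the count, reshuffling gave means of 8.65 and 8.58, and a central 95% of 5 to 13 at both times. Reshuffling covers counting error only. The libraries with and without ponesimod already differed in mix beyond it, so a value outside, in either direction, was likely. The weighted 24 h value carries gaps that weighting widened, from 1.63 to 6.03 points in cluster 4 and -2.37 to -8.08 in cluster 2. Variation between single libraries keeps the hypothesis open.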
